A study of Mus musculus with 6 samples.

How the data were processed

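The data were 6 Affymetrix mouse expression arrays, each of total RNA from 1 pool of dorsal root ganglion neurons. Per the labels, the pools belonged to 3 title codes (L3-B, control, 50 neurons; L3-S and L6-R, retrogradely labelled with DiI, 20 neurons) in 2 size classes (big, and medium to small diameter), 1 array each. The labels name an RNA isolation kit and give neither the tissue that DiI was placed in nor whether pools came from different animals. The deposited table gives the authors' values as linear signal intensity for each of 45037 probe sets and 64 control probe sets. The mean of each array after trimming 2% of values at each end was 150, so the table was taken as already scaled between arrays and was not normalized again. The summary method and the scaling step are not given in the sources used here. No detection calls were used here. Signals under 32, near the background of such arrays, made up 55.3% to 59.6% of an array's probe sets, and the median signal of an array was 18.8 to 25.2; differences between signals in that range cannot be resolved.

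Values were transformed as log2(signal + 32), which shrinks folds that involve low signals. Of the probe sets, 34945 carried 1 gene symbol, 932 carried several and 9160 none. For each of 18193 genes the probe set with the highest mean log2 value was used, and the upper 50% of genes by mean log2 value (9097 genes, minimum 6.41) were tested. Symbols were checked against a current gene table by gene identifier, which changed 0 of them. The chromosome of a named gene came from that table, and no coordinates are given. Some members of the fixed lists are not reported here.

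R 4.3.3 with limma 3.58.1 fitted 1 additive model of title code and size class to all 6 arrays (lmFit and eBayes, 2 residual degrees of freedom, 6.46 prior degrees of freedom, two-sided moderated test). The model assumes that the difference between codes is alike in both size classes, since with 1 array for each combination an interaction leaves no residual. The comparisons were big minus medium to small, L6-R minus L3-S, and the mean of L3-S and L6-R minus L3-B. P-values were adjusted by Benjamini and Hochberg over the genes tested, with a threshold of 0.05. No group had replicate arrays of the same code and size class, so the spread is what remains after the additive fit.

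Before the data were examined, 23 gene lists, the comparisons, the tests and the rule for naming genes were fixed; a first fit of this same design served to look at the data and the design was not altered. Of the lists, 13 were lists of symbols: markers of large myelinated-fibre neurons, of peptidergic nociceptors, of non-peptidergic and other small-diameter neurons, of satellite glia and Schwann cells, of connective tissue and vessels, and of blood and immune cells; nerve injury response genes; immediate early and heat shock genes; Hox genes of paralogue groups 1 to 8 and of groups 9 to 13; synaptic vesicle and release genes; cholesterol synthesis genes; and sex-linked genes. A further 10 were defined by symbol patterns: potassium, sodium and calcium channel subunits, TRP channels, GABA-A, ionotropic glutamate and nicotinic receptor subunits, serotonin receptors, oxidative phosphorylation subunits and cytosolic ribosomal proteins. A gene can be on more than 1 list (Gal, Jun and Trpv1, for example). The 21 lists with at least 3 tested members were tested with camera of limma at a preset correlation between genes of 0.01. P-values were adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. With an estimated correlation camera also refers its statistic to the 2 residual degrees of freedom. A list can then hardly pass after adjustment, whatever its correlation, so a failure there decides little.

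Named genes were, per comparison and direction, the 10 with the largest change among those past the threshold that moved the same way in every matched pair of arrays. Where fewer passed, up to 6 per direction with the smallest unadjusted p among genes moving the same way in every pair by at least 1 log2 were taken. From each list, up to 4 tested members with the smallest unadjusted p were added. Other named genes were chosen after their values were seen: Nefh and Pvalb in the size comparison, Cap1, Chodl, and Kit, Tac1, Hoxa5, Hoxb3, Hoxb6 and Hoxd8 in L6-R against L3-S. Of the genes named by rule, 111 had several probe sets. In 4 of them (Mbp, Runx1, Kcna6 and Cntnap2) probe sets shifted by at least 0.5 log2 in opposite directions. In L6-R against L3-S some genes had probe sets far apart, such as Sqor (3.67 and -0.31), and others had probe sets alike, such as Mical1 (2.63 and 2.50). Not every such gap is given below.

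Alternatives were quantile normalization, pseudocounts of 1 and 128, no filter and an upper 25% filter, the mean of a gene's probe sets, every probe set tested, eBayes with a trend or robust, array weights, fits to fewer arrays, a fit without the code, and leaving out each array in turn. The ratio of 3' to 5' Actb control signal as a covariate, the omission of the 2 arrays with the highest ratio (L3-B big and L3-S medium to small, fitted with code alone) and a list of interferon-response genes were added after the data were seen.

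The fit was tested on simulated data with the same layout, in which 200 of 9097 genes were changed by 2-, 4-, 8- or 16-fold (50 each), over 20 repeats. First, the truth was each gene's moderated variance from limma, which is already shrunk toward the prior. On average 7.84%, 7.81% and 6.20% of calls were then false for size, L6-R against L3-S and DiI against control. Of 2-fold changes 88.0%, 67.7% and 80.1% were called. With variances drawn from limma's prior, 4.58%, 4.88% and 4.86% of calls were false, and 51.3%, 21.8% and 40.1% of 2-fold changes were called. The simulated noise was independent for each gene and array, so these rates do not cover spread that genes share. In the real fit camera estimated correlations between genes of 0.41 for the ribosomal list and 0.49 for the glial list. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.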

Results

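RNA from pools of mouse dorsal root ganglion neurons was measured on 6 Affymetrix expression arrays. Dorsal root ganglia hold the cell bodies of the sensory neurons of the body. The arrays formed a layout of 3 title codes (L3-B, L3-S and L6-R) by 2 size classes (big diameter, and medium to small diameter), with 1 array for each combination. The L3-B pools held 50 control neurons each. The L3-S and L6-R pools held 20 neurons each that carried DiI, a lipophilic dye that axons take up and carry back to the cell body. The meaning of the codes, the site of the DiI and the number of animals were not given in the sources used here. The number of arrays limits the precision. Differences are those of log2(signal + 32). Differences and folds that involve signals near or under 32 are shrunk by the added 32, and the order of genes among them is not resolved. They are given with the standard error (SE) of a limma fit to all 6 arrays. The p-values measure only the spread between these pools, part of which can be technical.

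The ratio of 3' to 5' control signal differed between arrays. The Actb ratio, which can grow as RNA is less complete, was 13.9 in the L3-B big array and 3.73 in the L3-B medium to small array. It was 5.42 and 12.0 in the L3-S arrays (big, then medium to small) and 8.31 and 8.42 in the L6-R arrays. Dap, a spiked bacterial control transcript, also had far less 5' signal (37.0 to 295) than 3' signal (1019 to 6440) in every array. The Actb ratio therefore need not measure the completeness of the neuron RNA alone. Across genes, arrays of the same code and different size class correlated at 0.956 to 0.976 (3 pairs). Arrays of the same size class and different code correlated at 0.908 to 0.956 (6 pairs). Pairs that differed in code and size class correlated at 0.9072 to 0.9635 (6 pairs). The L3-B medium to small array was closer to L3-S big (0.9635) than to L3-B big (0.956). L3-B medium to small and L3-S big had the lowest Actb ratios (3.73 and 5.42). Each other array was closest to its own code, L3-B big only narrowly (0.956 against 0.9558 with L3-S big). Genes are not independent replicates. The first principal component held 49.9% of the variance and placed the L6-R arrays at 32.89 and 31.87, the L3-S arrays at -9.43 and -3.93, and the L3-B arrays at -24.33 and -27.06.

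L6-R neurons were set against L3-S neurons, the pair of codes that shared DiI labelling and the number of neurons per pool. L6-R neurons had high neuropeptide Y and almost no parvalbumin. Npy (chromosome 6), a neuropeptide that sensory neurons produce after axon injury, had signals of 849 and 1368 in the L6-R arrays (big, then medium to small) and 25 and 17 in the L3-S arrays. It rose by 4.39 ± 0.26 log2 (SE, n = 2 arrays per code, adjusted p = 0.000566), which is 21.0-fold higher by the point estimate. Pvalb (chromosome 15), a calcium-binding protein of muscle spindle afferents and other large sensory neurons, had signals of 69 and 32 in L6-R and 2084 and 3413 in L3-S. It fell by 5.07 ± 0.32 log2 (n = 2 arrays per code, adjusted p = 0.000566), which is 33.6-fold lower by the point estimate. Of the 9097 genes tested, 289 passed the adjusted p threshold of 0.05, of which 115 rose and 174 fell in L6-R. The sizes of these changes ran from 1.02 to 5.07 log2.

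Other large rises, several from L3-S signals near or under background, were those of Sqor, a mitochondrial sulfide-oxidising enzyme (3.67), Lgals3, a galectin (3.46), Tubb6, a beta-tubulin (3.35), Comp, an extracellular matrix protein (3.17), and Cartpt, the precursor of the CART peptides (2.95). Sox11, a transcription factor of developing and regrowing neurons (2.84), the ribonuclease Rnase4 (2.71), the oncostatin M receptor subunit Osmr (2.66) and Mical1, an enzyme that oxidises actin (2.63), were also among them. Other large falls, several to L6-R signals near or under background, were those of the protocadherin Pcdh8 (-3.86), the Rac regulator Chn2 (-3.52), the calcium-binding protein Caln1 (-3.36), the heparan sulfate sulfotransferase Hs3st2 (-3.32) and Ano1, a calcium-activated chloride channel (-3.20). S100a16 (-3.20), Clec2l (-3.18), the carbonic anhydrase Car2 (-3.11) and Stxbp6, a syntaxin-binding protein (-3.02), fell as well. The probe sets of Mical1, Pcdh8, Hs3st2, Ano1 and S100a16 are of designs that can bind more than 1 transcript.

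**Figure D1:**
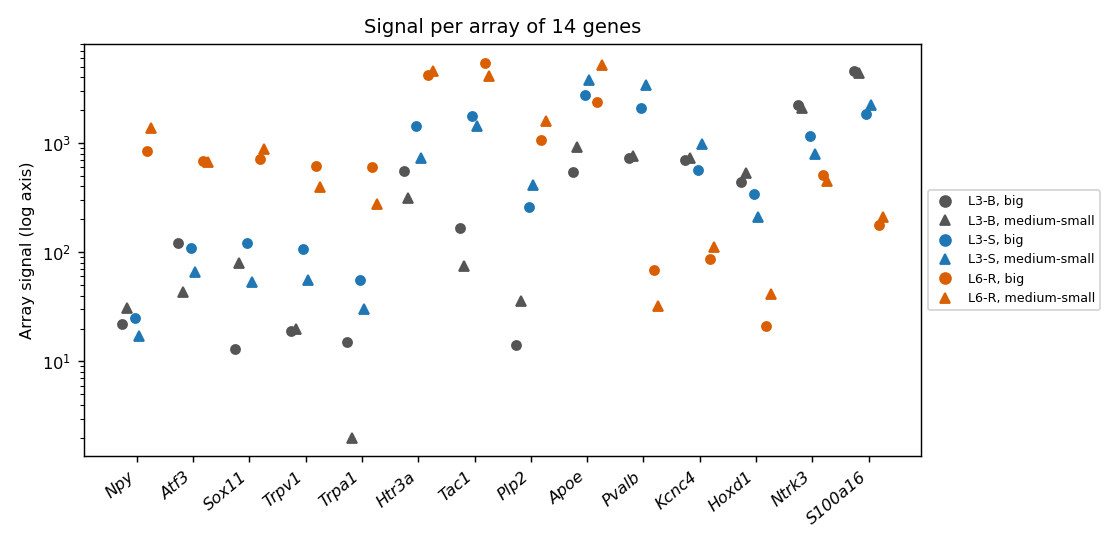
Array signal (log axis) of 14 genes, 1 point per array, coloured by title code and shaped by size class; there are no replicate arrays, so no error bars are drawn. Npy stood at 849 and 1368 in the L6-R arrays and at 17 to 31 in the others, while Pvalb stood at 69 and 32 in L6-R and at 723 to 3413 in the others.

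Genes of the nerve injury response rose together in L6-R. Of 14 tested members, 9 rose, 0 fell and 5 did not pass; adjusted over the list alone, 13 rose. The list's median was 1.35 log2 (limma camera adjusted p = 4.87e-16; adjusted p = 0.484 with an estimated correlation). Atf3, a transcription factor induced by axon injury, had signals of 680 and 674 in L6-R and 110 and 66 in L3-S and rose by 2.59 ± 0.28 (n = 2 arrays per code, adjusted p = 0.00254). Sox11 rose by 2.84 ± 0.43 (adjusted p = 0.0119) and the neuropeptide Gal by 1.63 ± 0.22 (adjusted p = 0.00742). Immediate early and heat shock genes had a median of 0.68, with 1 of 10 members rising over all genes and 3 adjusted over the list alone (camera adjusted p = 0.000201; adjusted p = 0.484 with an estimated correlation). Dusp1, a phosphatase of MAP kinases, rose by 1.39 (adjusted p = 0.0174), and Fos differed by 1.19 without passing (adjusted p = 0.133). Without the L6-R medium to small array that list's median was 0.20 and its call was lost.

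Markers of peptidergic nociceptors, the pain-sensing neurons that release neuropeptides, rose in L6-R. Of 12 tested members, 5 rose and 1 fell, and adjusted over the list alone 9 rose and 1 fell; the median was 1.08 (camera adjusted p = 1.78e-06; adjusted p = 0.484 with an estimated correlation). The irritant-gated channel Trpa1 rose by 2.57 ± 0.24 (adjusted p = 0.00155), the heat- and capsaicin-gated channel Trpv1 by 2.24 ± 0.25 (adjusted p = 0.00367), and Gfra3, the artemin co-receptor, by 1.74 ± 0.25 (adjusted p = 0.00858). Gal, also on the injury list, and Tac1 were the others of the 5, and the receptor kinase Kit fell (-1.42). Markers of non-peptidergic and other small-diameter neurons had a median of 0.32 with 1 of 10 members rising, Osmr, and 2 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.0241; adjusted p = 0.484 with an estimated correlation). That call was lost without the L3-S big array (median 0.39) and without the L6-R big array (0.31). Markers of large myelinated-fibre neurons had a median of -0.14 and a mean of -0.56, with Pvalb and the vesicle protein Vamp1 (-1.26, adjusted p = 0.0216) the 2 of 15 that fell, and 4 falling adjusted over the list alone (camera adjusted p = 0.0197; adjusted p = 0.484 with an estimated correlation). That call was lost without the L3-S medium to small array, where the median was -0.06. Ntrk3, a neurotrophin receptor, differed by -0.96 (adjusted p = 0.0717) and the sodium channel Scn1a by -0.74, neither past the threshold.

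Potassium channel subunits moved in both directions, with 16 of 37 members higher and 21 lower in L6-R. Over all genes 6 fell and 0 rose, and adjusted over the list alone 10 fell and 1 rose. The median was -0.13, with -0.24 in the big pair of arrays and -0.07 in the medium to small pair (camera adjusted p = 0.0211; adjusted p = 0.484 with an estimated correlation; fry adjusted p = 0.118), and the call was lost without the L3-S medium to small array (median -0.11). Kcnc4, a fast voltage-gated channel measured by a probe set that can bind more than 1 transcript, fell by 2.58 ± 0.25 (adjusted p = 0.00170), the A-type channel Kcnd3 by 2.17 (adjusted p = 0.00208), the leak channel Kcnk1 by 1.75 (adjusted p = 0.00661) and the channel-interacting protein Kcnip2 by 1.41 (adjusted p = 0.0351). Of 10 TRP channels 3 rose, also 3 adjusted over the list alone, namely Trpa1, Trpv1 and Trpv2 (1.15, adjusted p = 0.0333), and the median was 0.14 (camera adjusted p = 0.0161; adjusted p = 0.484 with an estimated correlation). Genes of synaptic vesicles and release had a median of -0.36, with Vamp1 and Sv2a (-1.25, adjusted p = 0.0487) the 2 of 18 that fell, and 3 falling and 1 rising adjusted over the list alone (camera adjusted p = 0.0241; adjusted p = 0.484 with an estimated correlation). Their call was lost without the L3-S medium to small array (median -0.24) and without the L6-R medium to small array (-0.22); Syp at -0.98 and Syt4 at 0.87 did not pass.

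Other receptor and channel lists did not pass as groups but held single genes that changed. Among 5 serotonin receptors Htr3a, a ligand-gated cation channel, rose by 2.05 ± 0.29 (adjusted p = 0.00919) with signals of 4166 and 4559 in L6-R and 1441 and 731 in L3-S, and the G-protein-coupled Htr1d fell by 1.22 (adjusted p = 0.0425); the list's median of -0.15 and its mean of 0.21 differed in sign. Of 12 genes with calcium channel subunit symbols (median 0.35), Cacna2d1, the target of gabapentin, rose by 1.62 (adjusted p = 0.0378). Cacng5 fell by 2.17 (adjusted p = 0.00749) and Cacng2 by 1.55 (adjusted p = 0.0256). These 2 are on the list by their symbols alone. The nicotinic subunit Chrna3 rose by 1.79 (adjusted p = 0.00905; list median 0.25 over 3 members) and the GABA-A subunit Gabrb1 by 1.70 (adjusted p = 0.0254; list median 0.42 over 5). None of 9 sodium channel subunits (median 0.14) and none of 7 ionotropic glutamate receptor subunits (median 0.11) passed; Scn9a stood at 1.06 (adjusted p = 0.0744), Scn10a at 1.09 and Grik1 at 0.67.

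Hox genes of paralogue groups 1 to 8, which mark position along the body axis, fell in L6-R. Of 8 tested members 3 fell and 0 rose, and 5 fell adjusted over the list alone; the median was -0.77 (camera adjusted p = 1.37e-05; adjusted p = 0.484 with an estimated correlation). Hoxd1 had signals of 21 and 41 in L6-R and 344 and 211 in L3-S and fell by 2.29 ± 0.30 (n = 2 arrays per code, adjusted p = 0.00666). Hoxc8 fell by 1.79 ± 0.25 (adjusted p = 0.00826) and Hoxb5 by 1.40 ± 0.23 (adjusted p = 0.0174). Hoxa7 at -0.94, Hoxa5 at -0.60, Hoxd8 at -0.44, Hoxb6 at -0.41 and Hoxb3 at -0.09 did not pass. The 4 tested members of groups 9 to 13 did not pass as a list (median -0.08, camera adjusted p = 0.861): Hoxd9 stood at -0.42, Hoxa10 at -0.12, Hoxa9 at -0.05 and Hoxc10 at 0.29.

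**Figure D2:**
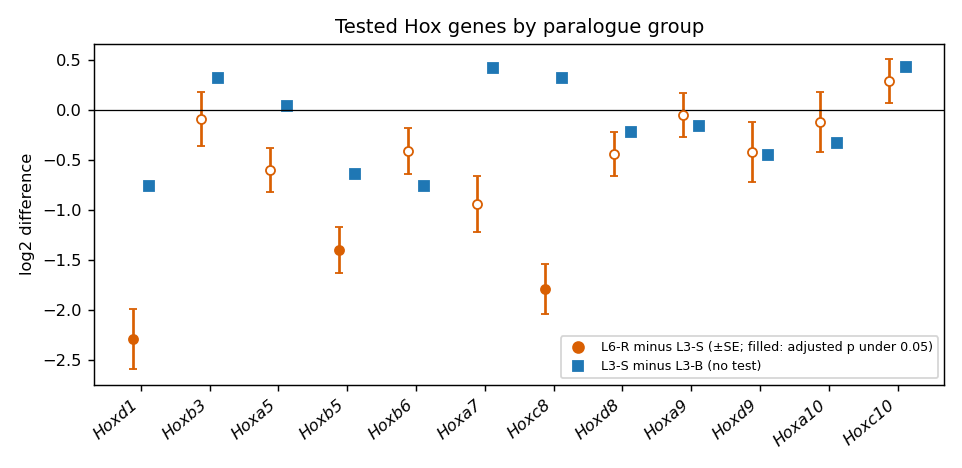
Log2 differences of the 12 tested Hox genes in order of paralogue group, for L6-R minus L3-S (circles, ± SE, filled where the adjusted p is under 0.05) and L3-S minus L3-B (squares, no test). Hoxd1, Hoxc8 and Hoxb5 fell in L6-R by 2.29, 1.79 and 1.40, while Hoxa9, Hoxa10, Hoxc10 and Hoxd9 lay between -0.42 and 0.29.

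Some lists of other cell markers and general transcript classes passed between these codes, with no member past the threshold over all genes. Satellite glia and Schwann cell markers had a median of 0.39, with 0 of 14 members past the threshold and 1 rising adjusted over the list alone (camera adjusted p = 0.0130; adjusted p = 0.531 with an estimated correlation). Their median was 0.04 in the big pair of arrays and 0.62 in the medium to small pair, and without the L6-R medium to small array it was 0.02 and the call was lost. Mal stood at 1.63 (adjusted p = 0.0515) and Mbp at 1.31, with other Mbp probe sets between -0.93 and 1.82. Connective tissue and vessel markers had a median of 0.59 over 6 members and did not pass (camera adjusted p = 0.161), with Dcn at 1.30 and Rgs5 at -1.59 (adjusted p = 0.0721). Cytosolic ribosomal protein genes had a median of 0.38 over 38 members (camera adjusted p = 3.44e-05; adjusted p = 0.518 with an estimated correlation) and oxidative phosphorylation subunits one of -0.24 over 70 (camera adjusted p = 0.00129; adjusted p = 0.563 with an estimated correlation), with 0 members of either past the threshold, also adjusted over the list alone. Rps6 stood at 0.99 and Uqcr11 at -0.81. The ribosomal call was lost without the L3-S big array (median 0.12), and the oxidative phosphorylation call without the L3-S medium to small array (-0.04) or the L6-R big array (-0.16). Cholesterol synthesis genes did not pass (median 0.17 over 13, Fdps at 0.78).

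Of 21 lists 12 passed with camera's preset correlation (7 up, 5 down) and 0 with an estimated one. Fry, which tests whether a list's genes move on balance one way and compares them with no other genes, also passed 0 (smallest adjusted p 0.0511, for the injury, the Hox 1 to 8 and the nicotinic lists). The gene count was 653 when either L3-B array was left out, 140 when either L6-R array was left out, 633 with array weights, 994 with the Actb ratio as a covariate, 148 with a pseudocount of 1, 107 with no filter on dim genes and 115 among the brightest 25% of genes. Of 43 named genes past the threshold, 31 passed with each array left out in turn; Vamp1, Dusp1, Hoxb5, Sv2a, Kcnip2, Cacng2, Cacna2d1, Trpv2, Gabrb1, Chrna3, Htr3a and Htr1d did not, 39 and 38 passing without the L3-S arrays (big, then medium to small) and 34 and 33 without the L6-R arrays.

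DiI labelled neurons of both codes were set against the L3-B control neurons. This comparison cannot be separated from the number of neurons pooled (20 against 50) or from the codes themselves. The substance P precursor gene was much higher in DiI labelled neurons. Tac1 (chromosome 6) had signals of 167 and 75 in L3-B, 1758 and 1429 in L3-S, and 5435 and 4090 in L6-R. It rose by 4.25 ± 0.21 log2 (SE, n = 4 arrays against 2, adjusted p = 0.000119), which is 19.0-fold higher by the point estimate. The other Tac1 probe set stood at -0.08. In all, 392 of 9097 genes passed, of which 279 rose and 113 fell with DiI. The share of rises depended on the setting, with 74 rising and 66 falling among the brightest 25% of genes and 152 rising and 19 falling with only the L3-S and L3-B arrays. The sizes of these changes ran from 0.83 to 4.25 log2.

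Other large rises, most from L3-B signals near or under background, were those of the membrane protein Plp2 (3.63), the water channel Aqp1 (2.99), Adcyap1, the precursor of the neuropeptide PACAP (2.95), the protease Pappa2 (2.88), the sodium pump regulator Fxyd2 (2.86) and the cell cycle inhibitor Cdkn1a (2.85). Cbln2, a synaptic organiser, Comp and Rarres1 each rose by 2.84. Fxyd2, Cbln2 and Rarres1 were at least as high in L3-S as in L6-R, with differences from L3-B of 3.17 and 2.54, of 3.39 and 2.29, and of 2.94 and 2.73. S100a16 fell by 2.73 ± 0.20, followed by the prostaglandin F receptor Ptgfr (-2.69), Insyn2b (-2.61), the matrix link protein Hapln1 (-2.56) and the copine Cpne4 (-2.29). Kcnq5, a channel of the M current (-2.05), the homeobox gene Meis2 (-2.01), Pcp4l1 (-1.98), Hoxd1 (-1.90) and the calcium buffer Calb1 (-1.85) fell as well. The probe sets of S100a16, Fxyd2 and Meis2 are of designs that can bind more than 1 transcript.

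Peptidergic nociceptor markers rose with DiI in the mean of both codes, by more in L6-R than in L3-S. Of 12 members 7 rose and 0 fell, and 8 rose adjusted over the list alone; the median was 1.16 (camera adjusted p = 1.48e-09; adjusted p = 0.537 with an estimated correlation). The 7 included Tac1, Adcyap1 (2.95 ± 0.21, adjusted p = 0.000542), Trpv1 (2.24 ± 0.22, adjusted p = 0.00148) and Trpa1 (2.18 ± 0.21, adjusted p = 0.00142). The list's median was 0.63 and 0.83 in L3-S (big, then medium to small) and 1.90 and 1.69 in L6-R. Non-peptidergic and other small-diameter markers did not pass as a list (median 0.59, camera adjusted p = 0.204), though Plxnc1, a semaphorin receptor, rose by 2.82 ± 0.19 and Runx1, a transcription factor of nociceptors, by 2.17 ± 0.28, with other Runx1 probe sets as low as -0.54. Osmr at 1.67 (adjusted p = 0.0556) and Cd55 at -0.91 did not pass. Large myelinated-fibre markers had a median of -0.48 over 15 members, with as many members rising (2) as falling (2), and 2 rising and 4 falling adjusted over the list alone (camera adjusted p = 0.00516; adjusted p = 0.537 with an estimated correlation). Ntrk3 fell by 1.63 ± 0.20 (adjusted p = 0.00352) and Vamp1 by 0.92 (adjusted p = 0.0359), while Cacna1h, a T-type calcium channel (1.54, adjusted p = 0.00665), and the neurotrophin receptor Ntrk2 (1.49, adjusted p = 0.0142) rose. That list's call was lost without the L3-B big array (median -0.26), and that of Ntrk2 without the L3-B medium to small array (1.07).

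Nerve injury genes rose in the comparison as a whole, mostly through L6-R. Of 14 members 6 rose and 0 fell, and 10 rose adjusted over the list alone; the median was 1.18 (camera adjusted p = 3.96e-09; adjusted p = 0.537 with an estimated correlation). The list's median differences from L3-B were 0.29 and -0.13 in L3-S (big, then medium to small) and 2.13 and 1.70 in L6-R. Npy rose by 2.05 ± 0.23 (adjusted p = 0.00249), but its difference from L3-B was -0.15 in L3-S and 4.24 in L6-R. Sprr1a rose by 1.74, Stmn4 by 1.58 and Gal by 1.15 (adjusted p = 0.0134). Immediate early and heat shock genes did not pass as a list (median 0.54 over 10, camera adjusted p = 0.0553), with Dusp1 rising by 1.08 (adjusted p = 0.0206).

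Markers of cells other than neurons rose with DiI alongside these genes. Of 14 satellite glia and Schwann cell markers 4 rose and 0 fell, and 6 rose adjusted over the list alone; the median was 0.75 (camera adjusted p = 0.000128; adjusted p = 0.629 with an estimated correlation). Apoe had signals of 540 and 913 in L3-B, 2764 and 3745 in L3-S, and 2394 and 5224 in L6-R and rose by 2.21 ± 0.21 (adjusted p = 0.00142). Fabp7 rose by 1.74 (adjusted p = 0.0187), Sox10 by 1.58 (adjusted p = 0.0198) and Mbp by 1.48 (adjusted p = 0.0495). The glial median was 0.13 and 0.29 in the big arrays (L3-S, then L6-R) and 0.62 and 2.00 in the medium to small arrays. Without the L3-B medium to small array it was 0.20 and the calls of the list, Fabp7 (1.01), Sox10 (0.97) and Mbp (0.66) were lost. Of 6 connective tissue and vessel markers 3 rose and 0 fell, and 5 rose adjusted over the list alone; the median was 1.26 (camera adjusted p = 1.57e-05; adjusted p = 0.582 with an estimated correlation). Rgs5, a pericyte gene, rose by 2.52 ± 0.33 (adjusted p = 0.00517), Dcn by 1.48 (adjusted p = 0.0244) and Col1a2 by 1.03 (adjusted p = 0.0400), the last 2 not past the threshold without the L3-B medium to small array (1.20 and 0.72), and Col1a2 also not without the L6-R medium to small array (0.89); Sparc stood at 1.51 (adjusted p = 0.0504).

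Among channels and receptors, subunits changed in both directions. The sodium channel beta subunits Scn3b and Scn2b rose by 2.29 ± 0.29 (adjusted p = 0.00453) and 2.11 ± 0.32 (adjusted p = 0.00896), in a list of 9 whose median of -0.04 and mean of 0.46 differed in sign. Of 37 potassium channel subunits 3 rose and 4 fell, and 9 rose and 10 fell adjusted over the list alone. Kcnq5 fell by 2.05 ± 0.20 (adjusted p = 0.00148), Kcnmb1, a subunit of calcium-activated channels, rose by 1.44 (adjusted p = 0.00844), and Kcna6 rose by 1.44 (adjusted p = 0.0190) with other Kcna6 probe sets down to -1.82 and a value of -0.09 when its probe sets were averaged. Kcnc4 fell by 1.22, through L6-R (-2.51) and not L3-S (0.07). The potassium channel median of 0.09 and mean of -0.01 differed in sign, and the list did not pass. Htr3a rose by 2.26 (adjusted p = 0.00249) and Htr3b by 1.47 (adjusted p = 0.0232), Chrna3 by 1.76 (adjusted p = 0.00404), Gabrb1 by 1.86 (adjusted p = 0.00781) and Gabrg1 by 1.03 (adjusted p = 0.0477). Their lists did not pass, with medians of -0.31 for 5 serotonin receptors (mean 0.36), 0.00 for 3 nicotinic and 0.02 for 5 GABA-A subunits, and neither did 7 glutamate receptor subunits (median -0.14, the test pointing up). Of 12 genes with calcium channel subunit symbols (median 0.11, not past), Cacna1h and Cacna1c (1.23, adjusted p = 0.0188) rose and Cacng2 fell by 1.34 (adjusted p = 0.0205). Of 10 TRP channels 3 rose, Trpv1, Trpa1 and Trpv2 (0.88, adjusted p = 0.0437), also 3 adjusted over the list alone, and the median was 0.37 (camera adjusted p = 0.0124; adjusted p = 0.582 with an estimated correlation); without the L3-B big array the median was 0.14 and the call was lost. Synaptic vesicle genes did not pass (median -0.19 over 18), though Syt1, the calcium sensor of release, rose by 1.84 (adjusted p = 0.00223) and Sv2a by 1.06.

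Hox genes of groups 1 to 8 fell in the comparison as a whole, mostly through L6-R. Of 8 members 3 fell, also 3 adjusted over the list alone, with a median of -0.51 (camera adjusted p = 0.000292; adjusted p = 0.537 with an estimated correlation). The list's median differences from L3-B were -0.10 and -0.20 in L3-S (big, then medium to small) and -0.93 and -0.79 in L6-R. Hoxd1 fell by 1.90 (adjusted p = 0.00587), Hoxb5 by 1.34 (adjusted p = 0.00901) and Hoxb6 by 0.96 (adjusted p = 0.0359), and Hoxc8 stood at -0.57, with 0.32 in L3-S and -1.47 in L6-R. Groups 9 to 13 did not pass (median -0.29 over 4). Oxidative phosphorylation subunits had a median of -0.12 (camera adjusted p = 0.00687; adjusted p = 0.696 with an estimated correlation), cytosolic ribosomal protein genes 0.22 (camera adjusted p = 0.0231; adjusted p = 0.696 with an estimated correlation) and cholesterol synthesis genes 0.30 (camera adjusted p = 0.0308; adjusted p = 0.599 with an estimated correlation), with 0 members of these 3 lists past the threshold, also adjusted over the list alone. In the pairs L3-S and L6-R big, then L3-S and L6-R medium to small, against L3-B, the log2 Actb ratio differed by -1.36, -0.74, 1.68 and 1.17, the oxidative phosphorylation median by -0.38, -0.46, 0.29 and -0.07, and the ribosomal median by -0.33, 0.18, 0.41 and 0.62. The oxidative phosphorylation median turned to 0.14 without the L3-B big array, and its call was lost without the L3-S big array (-0.03). The ribosomal median turned to -0.09 without the L3-B medium to small array, and its call was lost without the L3-S medium to small (0.15) or the L6-R medium to small array (0.19). The cholesterol call was lost without the L3-B big (0.17), the L3-S medium to small (0.16) or the L6-R big array (0.20).

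**Figure D3:**
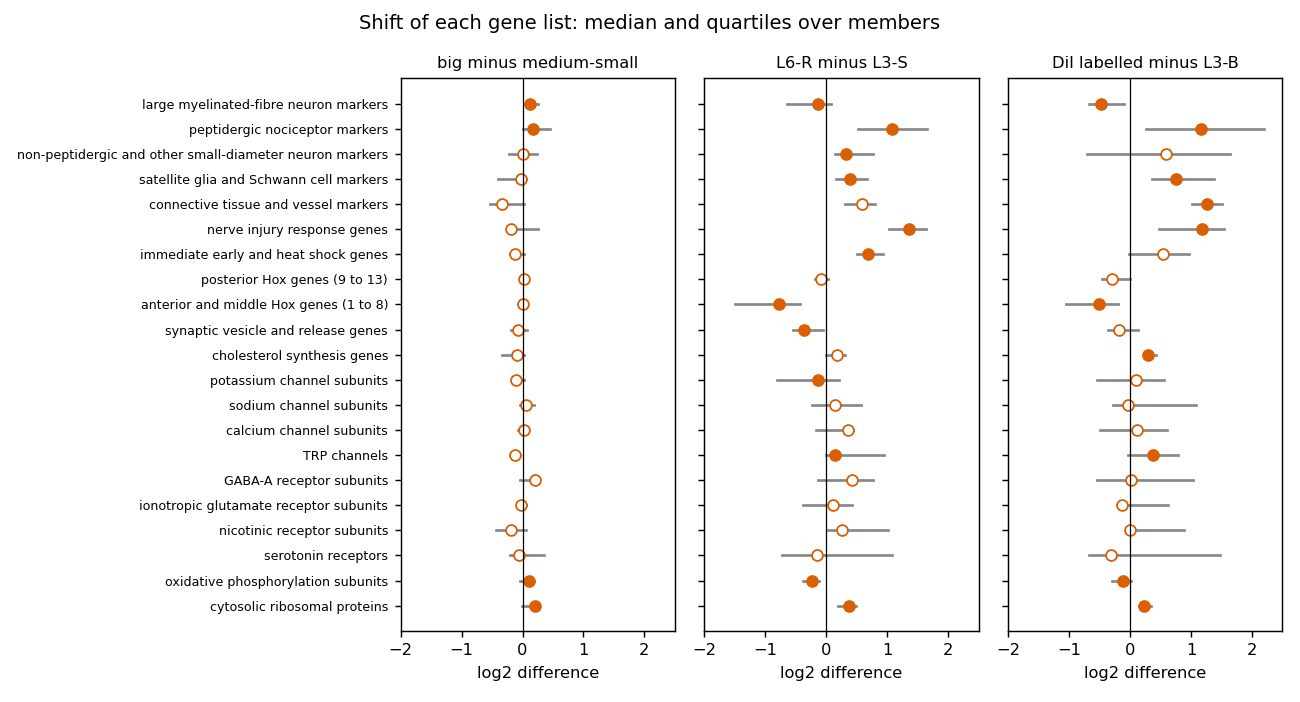
Median log2 difference (points) and quartiles (bars) over the members of each of the 21 tested gene lists, in the 3 comparisons; filled points passed camera with the preset correlation, and none passed with an estimated one. The injury list stood at 1.35 in L6-R minus L3-S and 1.18 in DiI labelled minus L3-B, and the size comparison's filled points lay between 0.10 and 0.20.

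Of 21 lists 10 passed with camera's preset correlation (7 up, 3 down), 0 with an estimated one, and 2 with fry, the peptidergic and the nicotinic lists (adjusted p 0.0398 each). The gene count was 590 without the L3-S big array, 171 with only the L3-S and L3-B arrays, 995 with only the L6-R and L3-B arrays, 258 with array weights, 1078 with the Actb ratio as a covariate, 255 with the mean of a gene's probe sets, 197 with no filter on dim genes and 140 among the brightest 25% of genes. Of 57 named genes past the threshold, 40 passed with each array left out in turn; besides those given above, Vamp1, Dusp1, Hoxb6, Sv2a, Kcnc4, Kcna6, Cacna1c, Cacng2, Trpv2, Gabrg1 and Htr3b did not, 52 and 43 passing without the L3-B arrays (big, then medium to small), 55 and 56 without the L3-S arrays and 53 and 51 without the L6-R arrays.

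Big neurons were set against medium to small neurons across the 3 codes. No gene separated the size classes: limma called 0 of 9097 genes (smallest adjusted p 0.998), while 320 had an unadjusted p under 0.05, 94 higher and 226 lower in big neurons, where 455 are expected by chance. Nefh, the heavy neurofilament of large neurons, differed by 0.18 ± 0.21 (n = 3 arrays per class), and Pvalb by -0.04 ± 0.26; these genes were chosen after their values were seen. The antiviral enzyme gene Rsad2 stood at -1.48 ± 0.32, the interferon-inducible GTPase gene Iigp1 at -1.51 and Oasl2 at -1.17. Fastk stood at -1.05 ± 0.21, the lysozyme gene Lyz1 at -1.11 and the growth factor gene Ptn at -1.01, and on the other side Anxa4, an annexin, at 1.10 ± 0.32 and Tpd52l1 at 1.07 ± 0.26. None of these genes passed.

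The list shifts between size classes were small, and no member of the fixed lists passed over all genes. Adjusted over the list alone, 1 of 7 glutamate receptor subunits, Grik1 (-0.89), and 1 of 3 nicotinic subunits, Chrna3 (-0.66), were lower in big neurons. Cytosolic ribosomal protein genes had a median of 0.20 over 38 members (camera adjusted p = 0.000429; adjusted p = 0.820 with an estimated correlation), with values of 0.61, -0.08 and 0.08 in L3-B, L3-S and L6-R. The log2 Actb 3' to 5' ratio, big minus medium to small, was 1.90, -1.15 and -0.02 in the same codes. Oxidative phosphorylation subunits had a median of 0.10 over 70 (camera adjusted p = 0.0253; adjusted p = 0.820 with an estimated correlation), with 0.50, -0.20 and -0.01 in the 3 codes, in the same order as the Actb differences. With either L3-B array left out, the ribosomal median was 0.00 and the oxidative phosphorylation median -0.08. Markers of peptidergic nociceptors (median 0.17 over 12, camera adjusted p = 0.0185; adjusted p = 0.820 with an estimated correlation) and of large myelinated-fibre neurons (0.13 over 15, camera adjusted p = 0.0268; adjusted p = 0.820 with an estimated correlation) passed upward. The large-fibre medians were 0.28, -0.09 and 0.11 in L3-B, L3-S and L6-R, also in the order of the Actb differences and with L3-S the other way. Among these markers Trpa1 stood at 0.68, Gfra3 at 0.55, Tac1 at 0.53, Ntrk2 at 0.50 and Cntnap2 at 0.50, with other Cntnap2 probe sets down to -0.63. The peptidergic call was lost with either L6-R array left out (median 0.24), and the large-fibre call with either L3-B array left out (0.04) or either L6-R array (0.11). Glial markers (median -0.03 over 14) and connective tissue markers (-0.34 over 6) did not pass, with Apoe at -0.76, Fabp7 at -0.86 and Igfbp7 at -0.85. Of the 4 lists that passed, 0 did so with an estimated correlation, fry (smallest adjusted p 0.650), quantile normalization or no filter on dim genes.

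Cap1 (-2.12, adjusted p = 0.0287) was the 1 gene past the threshold with either L3-S array left out, and Rsad2 (-2.02, adjusted p = 0.0230) the 1 with either L6-R array left out; Chodl (-1.40) and Iigp1 (-1.62), with an adjusted p of 0.0366 each, were the 2 with the Actb ratio as a covariate.

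The 2 lists too small for a set test were given as values. Csf1r, the 1 tested marker of blood and immune cells, stood at 0.80 in L6-R against L3-S, 0.35 in DiI against control and 0.39 in big against medium to small neurons, none past the threshold. Of the sex-linked genes, the Y-linked Eif2s3y had signals of 210 to 344 and Xist, expressed from the inactive X chromosome, of 11.4 to 44.3 in all 6 arrays. Eif2s3y and Kdm5d, the 2 tested, stood at 0.16 and -0.58 in L6-R against L3-S, and neither passed in any comparison.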

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

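The test of RNA quality on the size pattern and the count over other splits of the arrays were set before their results were seen. All other tests in this part were chosen afterwards. RNA quality in this part is read from the Actb ratio, with the limit given above. Bootstrap intervals in this part resample the genes of a list. They do not measure spread between pools, and the genes of a list can be correlated. The signal of a spiked bacterial control transcript (Dap, 3' probe set) was 6440 in the L6-R big array and 1019 to 3748 in the other 5, a value that no comparison uses. Among 2375 probe sets without a single gene name, of 22519 tested in all, 29 passed the threshold in L6-R against L3-S and 37 in DiI labelled against control.

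The nerve injury list was higher in L6-R than in L3-S by a median of 1.35 log2. The pairs of arrays argued against RNA quality as the whole cause, since the log2 Actb ratio was higher in L6-R by 0.62 in the big pair and differed by -0.51 in the medium to small pair, while the list's median was 1.29 (95% bootstrap interval over genes 0.92 to 1.76) and 1.5 (1.07 to 2.05). Glia carried into the L6-R pools would raise glial markers as much, yet the injury list exceeded the glial list by 0.96 (95% bootstrap interval over genes 0.52 to 1.44), with glial medians of 0.04 and 0.62 in the size classes. DiI labelling alike in both codes would raise the list in L3-S too. The list's rise over L3-B there (0.24) was 12.6% of that in L6-R (1.87, interval of the share -13.4% to 31.1%). The site of the DiI is not given, so labelling that differed between the codes is not covered. A response to axon injury stays open as a hypothesis that was not tested, since no label names an injury. Neuron-type markers also differed between these codes, with a peptidergic list median of 1.08, Pvalb at -5.07, and Gal on both the injury and the peptidergic list. Whether a different mix of neuron types carried part of the injury list's shift was not tested.

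Hox genes of groups 1 to 8 were lower in L6-R than in L3-S by a median of -0.77 log2. RNA quality as the whole cause was again argued against by the pairs, whose Actb ratios differed in opposite directions while the median was -1.01 (95% bootstrap interval over genes -1.84 to -0.51) and -0.56 (-1.73 to -0.31). Fewer neurons per pool is excluded by the design, as the number of neurons per pool differed by 0 between the codes. Both codes were DiI labelled, but the site of the DiI is not given, so labelling that differed between them cannot be excluded. Another axial level of the L6-R neurons stays open, and no label gives the axial level. In L6-R, 6 of 8 members were lower in both arrays than in all 4 others, as 16% of all tested genes were. That count was chosen after the fall against L3-S was seen and uses the same members, so it partly restates that fall. The 4 tested members of groups 9 to 13 (Hoxa9, Hoxa10, Hoxc10 and Hoxd9, median -0.08) ran from -0.42 to 0.29. No shift was predicted for them, so they do not decide it. Neuron-type markers also differed between these codes, and this was not separated from the Hox shift.

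No gene passed between size classes (limma 0 of 9097, 320 at an unadjusted p under 0.05). RNA quality hiding many genes was argued against by the Actb covariate, with which 2 genes passed. A spread too large for smaller differences cannot be told apart from their absence. The smallest difference that the same fit called was 1.02 log2 in L6-R against L3-S and 0.83 in DiI against control. The median size of all differences between size classes was 0.14. In the simulated size comparison, with independent noise, 51.3% to 88.0% of 2-fold changes were called. That simulation changed 200 of 9097 genes, by up to 16-fold. The many large changes ease the Benjamini and Hochberg adjustment for the 2-fold genes, whereas the real size comparison had 0 calls. The rate therefore does not give the chance of calling a few 2-fold changes between the real size classes. A similar mix of neuron types in both size classes may explain why no gene passed. The shift of large-fibre markers minus that of peptidergic markers was -0.04 (95% bootstrap interval over genes -0.35 to 0.20). This value was chosen afterwards and partly restates the lack of differences, as the medians of the 2 lists were 0.13 and 0.17, so it cannot decide the question. The 10 splits of the 6 arrays into 3 against 3 are too few for a share under 0.05. With the code term fitted there were 0 genes in the real split and 0 in the highest of the others. Without that term the split of both L3-B arrays and L3-S big from the rest gave 6, and the real split 0. With a real count of 0 every split gives as many whatever the data. Differences in how neurons were sorted by diameter were not tested.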

How the results depend on the processing

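The Actb covariate and the omission of the 2 arrays of highest Actb ratio were chosen after the results were seen; all other settings were planned. Of 6221 recomputed values of named genes and lists, 5662 kept their side of the threshold, 316 lost and 230 gained a call, and 13 reversed. The 5662 include values that passed in neither setting, among them 1490 of genes in the size comparison, where no gene passed. The total therefore does not measure how often a call was kept. A value counted as reversed if its sign changed and it passed in the main fit or in the alternative. Values that passed in neither were not checked for direction. For the estimated correlation and fry only the call was recomputed. The median of all genes moved by less than 0.1 log2 in every setting. Genes between size classes (0) became 2 with the Actb covariate and 0 to 1 with each array left out in turn. Genes in L6-R against L3-S (289) became 148 with a pseudocount of 1, 107 with no filter and 115 among the upper 25% (other numbers of genes tested), 633 with array weights (0.551, 0.845 and 2.15 for L3-B, L3-S and L6-R), 653 with only the 4 DiI arrays, 994 with the Actb covariate, and 140 (either L6-R array left out) to 653 (either L3-B array left out) with each array left out. Genes in DiI against control (392) became 197 with no filter, 140 among the upper 25% (74 up, 66 down, against 279 and 113), 255 with mean probe sets, 258 with array weights, 171 with only L3-S and L3-B (152 up, 19 down, 130 shared), 995 with only L6-R and L3-B, 1078 with the covariate, and 334 to 590 (without L3-S big) with each array left out. Without the 2 arrays of highest Actb ratio these counts were 318 (165 up, 153 down, against 115 and 174) and 307. Lists between size classes (4) became 0 with an estimated correlation, fry, quantile normalization or no filter, 1 among the upper 25%, and 2 with mean probe sets or without the code term; all 4 were up, but array weights gave 5 (2 up, 3 down, 2 shared with the 4), the covariate 5 (3 up, 2 down, 3 shared), either L3-B array left out 4 (1 up, 3 down, 1 shared) and either L6-R array left out 3 (2 up, 1 down, 2 shared). Lists in L6-R against L3-S (12) became 0 with an estimated correlation or fry. Lists in DiI against control (10) became 0 with an estimated correlation, 2 with fry, 6 among the upper 25% and 3 with only L3-S and L3-B. Reversed between size classes were the oxidative phosphorylation median (0.10; -0.08 to 0.26 with each array left out, -0.08 with either L3-B array left out) and the ribosomal median (0.20; 0.00 to 0.35, 0.00 with either L3-B array left out). Reversed in DiI against control were oxidative phosphorylation (-0.12; -0.41 to 0.14, 0.14 without L3-B big; 0.01 with only L3-S and L3-B; 0.04 without the 2 arrays of highest Actb ratio), ribosomal proteins (0.22; -0.09 without L3-B medium to small, to 0.56), potassium channels (-0.54 among the upper 25%), nicotinic subunits (0.13 with no filter), Npy (-0.15) and Kcnc4 (0.07) with only L3-S and L3-B, and Kcna6 (-0.09 with mean probe sets). Fits to only some codes leave out the arrays that carried those changes; for the rest the cause was not tested. With each array left out a code keeps 1 array, which is assumed to vary like the others. Injury, peptidergic, Hox 1 to 8 and TRP lists in L6-R against L3-S, and connective, peptidergic, injury and Hox 1 to 8 lists in DiI against control, kept their call with each array left out. Low signal over background limits what can be seen, since 55.3% to 59.6% of an array's probe sets lay under 32.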

Other observations

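The list of interferon-response genes and its test were chosen after the size comparison had been seen. Genes induced by interferon had lower signals in big than in medium to small neurons, without passing a test that estimates the correlation between genes (camera p = 0.0526; fry p = 0.0824). Of 20 tested members 18 were lower in big neurons, with a median of -0.40 log2 and medians of -0.53 in L3-B, -0.66 in L3-S and -0.21 in L6-R (1 array per size class in each). Rsad2, an antiviral enzyme, had signals of 27, 49 and 110 in the big arrays of L3-B, L3-S and L6-R and of 177, 347 and 156 in the medium to small arrays. Iigp1, an interferon-inducible GTPase, differed by -1.51 ± 0.36, and Oasl2 by -1.17 ± 0.26. No member passed limma's adjusted threshold in the size comparison with all arrays.

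The list was written after 6 of its members had been noticed, so the other 14 were tested alone. Their median was -0.30, with 12 lower in big neurons and medians of -0.27, -0.46 and -0.14 in L3-B, L3-S and L6-R. Camera gave p = 4.00e-05 with its preset correlation and p = 0.0736 with an estimated one, and for all 20 members 1.05e-12 and 0.0526. An interferon response that differs with the size class may be present, but the estimated correlation leaves it undecided, and the rule that read this test was worded after the p of the full list was known. The glial list had a median of -0.03, with 0.39, -0.16 and -0.75 in L3-B, L3-S and L6-R, an order unlike that of the interferon genes and opposite in sign in L3-B.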
